A study of Mus musculus with 8 samples.

How the data were processed

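Total RNA of mouse bone marrow derived macrophages was measured on 8 one-colour arrays, 1 for each combination of genotype (wild type or Vdr-/-), IFN-gamma and calcitriol. The deposited values were linear probe set intensity signals, and the authors had scaled each array to the same 2% trimmed mean, as the values show (150.07 to 150.08). The software, the scaling method, the doses of IFN-gamma and calcitriol and detection calls are not given in the sources used here. The labels also describe elicited peritoneal cells, but each sample's source names bone marrow derived macrophages. Treated cells were cultured for 24 to 48 hours, and no single time is given. Signal over background and the number of arrays limit the precision, as 15.5% of the tested values were at the floor.

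Of 22690 probe sets, 64 controls were set aside, which left 22626. Signals below the pooled 25th percentile (15.5) were set to it, log2 was taken, and probe sets whose highest signal reached the pooled median (59.1) were tested, 18054 in all. The annotation gave 1 gene for 20380 probe sets, several genes for 691 and none for 1555, and these last 2 kinds stayed in the tests unnamed. A gene with several probe sets was represented by the brightest. Signal ratios of 3' to 5' control probe sets served as a check of RNA truncation.

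Tests used limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all tested probe sets at 0.05. The IFN-gamma and genotype effects were each fitted over 4 array pairs as blocks (3 residual degrees of freedom). Calcitriol effects, their difference and the difference in IFN-gamma effect came from a fit nested in genotype (2 residual degrees of freedom). Its spread is the interplay of the treatments, so a gene with such interplay is harder to call. Calcitriol in single wild-type pairs took its spread from the Vdr-/- arrays (2 residual degrees of freedom). That assumes that calcitriol has no effect in Vdr-/- cells and that the genotypes vary alike. The 35 probe sets called for calcitriol in Vdr-/- leave the first assumption in doubt, and 0 were called there with the labels of the untreated arrays exchanged. Genotype cannot be told apart from the mice or cultures used.

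The comparisons, the 22 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Named genes were the 10 largest rises and 10 largest falls among the called genes of each contrast, a set of genes always reported where they had a singly named probe set (Vdr, Cyp24a1, Irf1, Ciita, Nos2, Cd74, Cxcl9, Tnf, Il12b and Cd14), and up to 4 members of each list described. Lists were tested with limma's fry, which asks whether a list's genes move one way on balance, adjusted over the lists, and its mixed version asks for changes in either direction. For genes induced by IFN-gamma in the other genotype, the median change with calcitriol was set against 10000 random sets matched on signal, with a bootstrap interval over 2000 draws.

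Alternatives were quantile normalization, no filter or a stricter one (pooled 75th percentile), floors at the 10th and 40th percentiles, no intensity trend, fits without blocks or with additive covariates, each pair left out in turn, and another source of spread for single pairs. Chosen after seeing the data were the Gapdh ratio as a covariate, leaving out the 2 arrays with the highest 3'/5' ratios, exchanging the labels of the 2 untreated arrays, additive fits for calcitriol (1 of them by genotype on the other 6 arrays, with 1 residual degree of freedom) and the comparison of 1 IFN-gamma array with the other 3. That comparison took probe sets with a mean signal at or above 59.1 and at most 1 of the 3 arrays at the floor, a limit set after a first version had given 346 calls.

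The fits were tested on simulated data with 200 changed probe sets among 18054. With noise at limma's moderated spread, changes of 2 log2 were recovered in 80% of cases for IFN-gamma, 60% for genotype, 54% for calcitriol in wild type, 38% for the difference and 2% for calcitriol under IFN-gamma, with 10, 7, 8, 4 and 0 false calls. With noise at each probe set's own residual spread, tried first, the shares were 48% and 32% for IFN-gamma and genotype and 0% for each calcitriol fit, even at 4 log2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.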

Results

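Gene expression was measured in mouse bone marrow derived macrophages, which were grown from marrow with the growth factor M-CSF at 50 ng/ml for 7 days. The series crossed 2 genotypes with IFN-gamma, the cytokine of classical macrophage activation, and calcitriol, the hormonally active form of vitamin D. The genotypes were wild type and Vdr-/-, a knockout of the vitamin D receptor gene Vdr. This gave 8 groups with 1 array each, and treatments lasted 24 to 48 hours. No group had a replicate, so the main tests rested on contrasts repeated across the other factors, and tests of single pairs borrowed their spread from other arrays. The number of arrays limits the precision of every value.

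Median signal per array ran from 53.5 to 68.3, and the 2% trimmed mean from 150.07 to 150.08. Of 22626 probe sets without controls, 18054 passed the signal filter, and they included a probe set for 10437 named genes. Log2 signals across these probe sets correlated between pairs of arrays with Pearson's r of 0.741 to 0.897, and probe sets are not independent replicates. The array labelled wild-type calcitriol had r of 0.741 to 0.781 with the others, and the array labelled Vdr-/- untreated had 0.77 to 0.809. The other 6 arrays had r of 0.815 to 0.897 among themselves. The same 2 arrays had the highest 3'/5' signal ratios, which rise when labelled RNA is truncated towards its 3' end. The Gapdh control ratio was 7.67 on the wild-type calcitriol array and 4.82 on the array labelled Vdr-/- untreated. It was 3.06 on the Vdr-/- IFN-gamma array and 0.853 to 1.65 on the other 5 arrays.

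**Figure D1:**
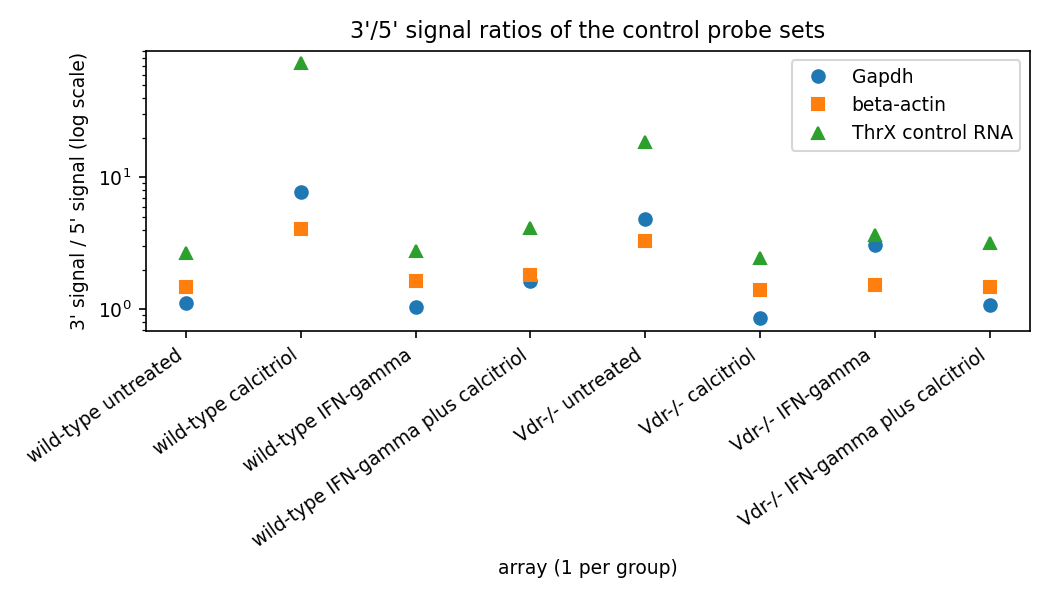
Ratio of 3' to 5' signal (log scale) of the Gapdh, beta-actin and ThrX control probe sets on each of the 8 arrays, 1 point per array. The ThrX ratio was 72.8 on the wild-type calcitriol array and 18.4 on the array labelled Vdr-/- untreated, against 2.46 to 4.14 on the other 6 arrays.

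Vdr, the gene targeted in the knockout, read at most 118.1 on 7 of the 8 arrays and did not follow the labels of the untreated arrays. Its brighter probe set read 6.7 on the array labelled wild-type untreated and 90.3 on the array labelled Vdr-/- untreated. A second Vdr probe set read 5.3 and 63.2 on these arrays. In the other 3 treatments both Vdr probe sets were higher in wild type. With calcitriol the first read 51.5 in wild type and 2.6 in Vdr-/-, with IFN-gamma 84.4 and 45.6, and with both 226.7 and 25. The second read 118.1 and 9.8, then 82.9 and 2.5, then 385.9 and 23.6. The position of these Vdr probe sets against the deleted part of the gene is not given in the sources used here, so they may check nothing about the genotype. Every calcitriol contrast without IFN-gamma used an array labelled untreated, and its direction rests on those labels.

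IFN-gamma was compared with no IFN-gamma to ask which genes the cytokine changes in these macrophages. Interferon-inducible GTPase and antigen presentation genes rose, chemokine genes went both ways, and a group of lipid handling genes fell. Cxcl9, a chemokine that attracts activated T cells, rose by 7.97 log2 (SE 0.271, limma adjusted p = 4.35e-16), with 3 of the 4 arrays without IFN-gamma at the floor. Iigp1, a GTPase that acts on pathogen vacuoles, rose by 6.85 log2 (SE 0.229, adjusted p = 4.35e-16), which is 116-fold. Mmp12, the macrophage elastase, fell by 5.72 log2 (SE 0.274, adjusted p = 3.05e-13). Each of these genes moved the same way in 4 of 4 array pairs, which a test whose spread is the disagreement of these pairs favours.

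The test called 619 probe sets, 389 higher and 230 lower with IFN-gamma, for 281 and 173 named genes. Of these 619, 598 moved the same way in all 4 pairs, which a spread taken from the disagreement of the pairs makes likely. In all, 2243 probe sets had an unadjusted p under 0.05. Among the 10 genes with the largest rises, the guanylate-binding proteins Gbp2, Gbp8 and Gbp6 rose by 6.82, 5.84 and 5.74 log2. Gbp2b was at the floor on all 4 arrays without IFN-gamma and was at least 224-fold higher with it. Acod1, which makes the antibacterial metabolite itaconate, was also at the floor without IFN-gamma and was at least 93.7-fold higher with it. AW112010, Plbd1 and Fgl2 rose by 6.62, 4.92 and 4.87 log2. Among the largest falls were the scavenger receptor family gene Cd5l (-3.42 log2), the chemokine gene Ccl9 (-3.12), the fatty acid binding protein gene Fabp4 (-3.06) and the transferrin receptor gene Tfrc (-2.70). Emp1 (-3.25 log2), Fcrls (-3.14), Cdkn1c (-3.06), Dio2 (-2.80) and Angptl4 (-2.71) also fell, and all of these but Fcrls had 1 to 3 arrays with IFN-gamma at the floor, which the size of the fall depends on. Irf1, a transcription factor of the interferon response, rose by 3.69 log2 (adjusted p = 1.91e-11). The log2 change was 1.43 for Tnf (adjusted p = 0.0697), 0.08 for Nos2 (0.984), -0.37 for Il12b (0.877) and -0.78 for Cd14 (0.11). It was 1.07 for Vdr (0.566) and -0.38 for Cyp24a1, the calcitriol-degrading enzyme (0.871), whose second probe set went the other way.

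Interferon-inducible GTPases, which defend cells against intracellular microbes, rose for 11 of 11 measured genes, and for 11 adjusted over the list alone (limma fry adjusted p = 0.000948). In MHC class II presentation, which shows peptides to CD4 T cells, 7 of 11 genes rose, and 8 adjusted over the list alone (0.000948). Its master regulator Ciita rose by 4.44 log2 (adjusted p = 9.57e-08), H2-Eb1 by 3.79 log2 and the invariant chain gene Cd74 by 2.23 log2 (adjusted p = 4.97e-07). In MHC class I presentation and the immunoproteasome, 11 of 15 genes rose, and 11 adjusted over the list alone (0.0222), such as Psmb8 by 3.88 log2 and Tap1 by 2.96 log2. Among IFN-gamma signalling genes, 8 of 16 rose, and 8 adjusted over the list alone (0.00428), such as the feedback inhibitor Socs1 by 3.73 log2 and Stat2 by 2.59 log2. Of the type I interferon-stimulated genes, 10 of 24 rose, and 17 adjusted over the list alone (0.0319), such as Ifit2 by 4.54 log2 and Zbp1 by 3.81 log2. Values at the floor of 15.5 count as 15.5 in these lists.

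Among chemokine genes, Cxcl10 rose by 4.84 log2, Ccl8 by 3.34 log2 and Ccl5 by 2.48 log2, while Ccl9 fell by 3.12 log2. Of 17 chemokine genes 6 rose and 2 fell, the same counts adjusted over the list alone, and fry gave an upward adjusted p of 0.0251 although the list's median was -0.10 log2. Of 20 activation surface receptors 7 rose, and adjusted over the list alone 7 rose and 3 fell (0.0222), with the Fc receptor gene Fcgr4 up 3.03 log2, the checkpoint ligand gene Cd274 up 2.78 log2 and Cd40 up 2.51 log2. Of 18 cytokine genes 2 rose and 1 fell, and 3 and 1 adjusted over the list alone (0.0143). Among these, the IL-18 inhibitor gene Il18bp rose by 3.45 log2. Of 17 antimicrobial and oxidant genes 3 rose, and 4 adjusted over the list alone (0.0322), among them Ncf1 by 1.18 log2 and Slc11a1 by 0.80 log2. Of 18 hypoxia and glycolysis genes 2 rose, and 3 adjusted over the list alone (0.0418), with Pfkp up 1.41 log2 and Pkm up 1.26 log2.

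Cholesterol and lipid handling genes fell for 6 of 25, and for 11 adjusted over the list alone (fry adjusted p = 0.00428), such as the lipid droplet gene Plin2 (-1.78 log2) and Hmgcs1 (-1.41 log2). The alternative activation list was mixed, with 2 of 12 genes higher and 3 lower, and 2 and 4 adjusted over the list alone (0.262). In it the mannose receptor gene Mrc1 fell by 1.95 log2 and Tgm2 rose by 2.31 log2. Of 21 macrophage identity genes 5 rose and 2 fell, and 7 and 4 adjusted over the list alone (0.375), with the complement gene C1qa up 1.74 log2 while Ctsl fell by 1.37 log2. The median of this list was -0.066 log2, while its mean was 0.157 and fry pointed up. Of 30 cell cycle genes 2 rose, Ube2c by 2.60 and Ccnb2 by 2.34 log2, and 7 adjusted over the list alone (0.262). Of 16 heat shock and immediate early genes 2 fell, Dusp1 (-2.39 log2) and Fos (-1.94 log2), and 3 adjusted over the list alone (0.117). Of 21 genes of the vitamin D receptor axis 2 rose and 1 fell, and 2 and 2 adjusted over the list alone (0.576). Nrip1 rose by 1.34 log2, Cdkn1a by 0.97 log2, and Gadd45a fell by 1.48 log2.

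Stromal and neutrophil markers moved down on balance, with medians of -1.36 and -0.556 log2, although few passed the test gene by gene. Of 10 stromal markers 1 fell, the collagen gene Col3a1 (-2.02 log2), and 5 adjusted over the list alone (fry adjusted p = 0.0188). Of 11 neutrophil and granulocyte precursor markers 0 passed the limma test, and 1 fell adjusted over the list alone (0.0188). Of 8 dendritic cell markers 1 rose, Cd83 by 1.74 log2, and adjusted over the list alone 1 rose and 1 fell (0.194). Of 13 lymphocyte and NK cell markers, and of 10 erythroid, megakaryocyte and mast cell markers, 0 passed the limma test over all genes or adjusted over the list alone (fry adjusted p = 0.939 and 0.118). Of 11 housekeeping genes 1 fell, Tfrc, and 1 adjusted over the list alone (0.926), with a median of 0.196 and a mean of -0.0269 log2.

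Without the 2 arrays with the highest 3'/5' ratios, limma called 0 probe sets for IFN-gamma with 1 residual degree of freedom (1395 at an unadjusted p under 0.05), and 53 with additive covariates, 52 of them among the 619. The count was 99 without the Vdr-/- pair that lacked calcitriol, 123 without the wild-type pair with calcitriol, 152 without the wild-type pair that lacked it, 80 without the signal filter and 70 without the intensity trend.

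**Figure D2:**
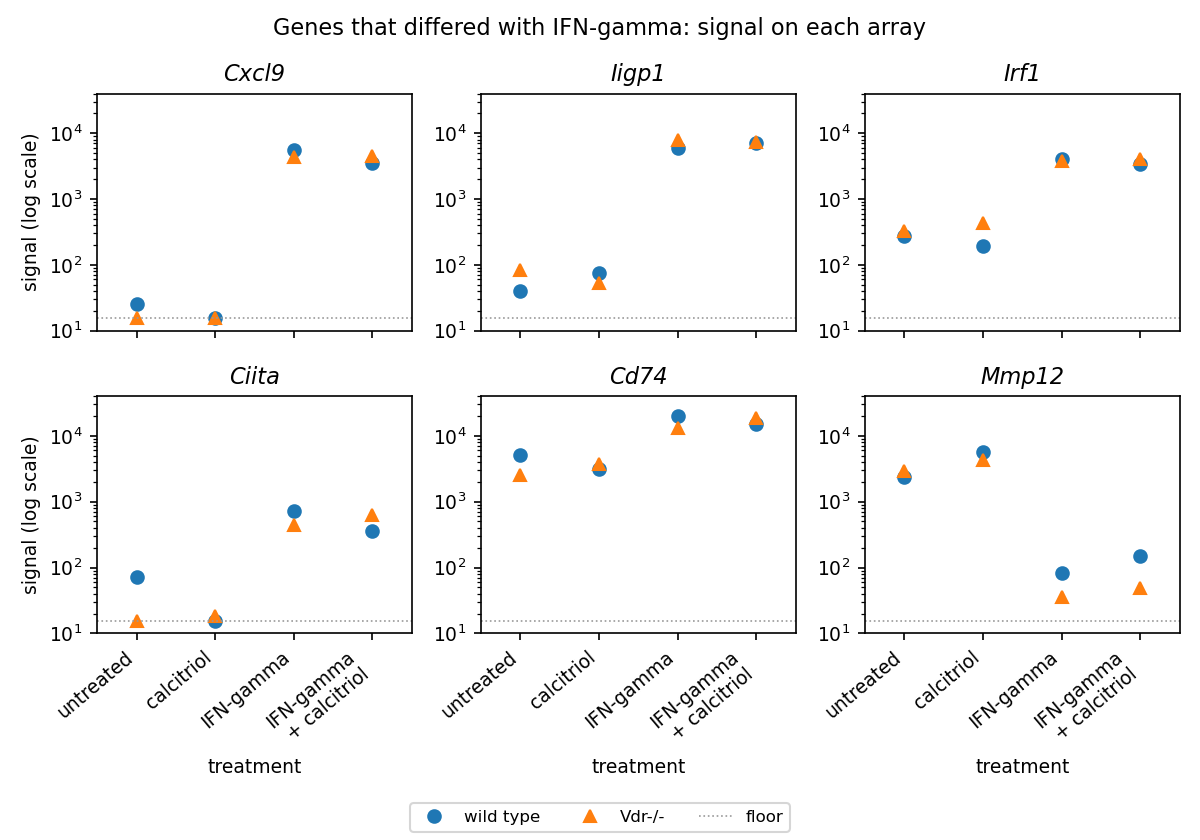
Probe set signal (log scale, floor of 15.5 as a dotted line) of 6 genes that differed with IFN-gamma, by treatment, with 1 point per array for wild type and for Vdr-/-. Cxcl9 read 3527 to 5633 on the 4 arrays with IFN-gamma and at most 25.4 without, while Mmp12 read 35.1 to 149.9 with it and 2331 to 5625 without.

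Calcitriol was compared with no calcitriol in wild-type cells, without and with IFN-gamma, to ask which genes the hormone changes where its receptor is present. Cd14, C5ar1 and Trem2, which encode cell surface receptors, were among those that fell. Cd14, the lipopolysaccharide co-receptor, fell by 2.16 log2 (SE 0.366, limma adjusted p = 0.00646), which is 4.46-fold. C5ar1, the receptor for complement C5a, fell by 3.55 log2 (SE 0.691, adjusted p = 0.018), and the transcription factor gene Klf6 fell by 3.43 log2 (SE 0.567, adjusted p = 0.00548). Hopx, a homeodomain-like regulator, rose by 2.54 log2 (SE 0.498, adjusted p = 0.0181), and 4931406C07Rik by 2.90 log2 (SE 0.384, adjusted p = 0.002). With the mean over a gene's probe sets in place of the brightest, Cd14, C5ar1, Trem2, Klf6, Hopx and 4931406C07Rik were no longer called.

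The test called 104 probe sets, 34 higher and 70 lower, for 26 and 59 named genes, and 1857 had an unadjusted p under 0.05. All 104 moved the same way in both wild-type pairs, which a spread taken from the disagreement of the pairs makes near certain. Among the other largest rises, Ifitm6 rose by 3.76 log2, Bhlhe40 by 2.98 log2, Ugcg, which makes glucosylceramide, by 2.97 log2, and the necroptosis kinase gene Ripk3 by 2.78 log2. Hsph1, Dipk2a, Crip1 and Mrc1 rose by 2.32, 2.02, 2.02 and 1.92 log2. Among the other largest falls, Pck2, the mitochondrial PEPCK gene, fell by 3.77 log2, and the immunoproteasome gene Psmb8 fell by 3.01 log2, while Il3ra was at the floor on both arrays with calcitriol and at least 9.25-fold lower. Also lower were Tspan17 (-2.96 log2), 1600014C10Rik (-2.95), the phospholipid transfer protein gene Pltp (-2.75), the lipid receptor gene Trem2 (-2.68) and Fgd2 (-2.58). C5ar1, Psmb8, Tspan17 and Fgd2 were at the floor on the wild-type calcitriol array, so the size of these falls depends on the floor. The same holds for the rises of Ifitm6 and Bhlhe40, at the floor on the wild-type IFN-gamma array, and of Ugcg and Ripk3, at the floor on the array labelled wild-type untreated. The log2 change was 1.5 for Cyp24a1 (adjusted p = 0.592) and 1.58 for Vdr (0.565). It was -0.40 for Irf1 (0.713), -1.62 for Ciita (0.319), -0.53 for Cd74 (0.66) and -0.69 for Cxcl9 (0.572). It was 1.07 for Nos2 (0.739), 0.66 for Tnf (0.74) and 1.24 for Il12b (0.711).

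No gene list passed the fry test for movement in 1 direction in this contrast, and the lowest fry adjusted p was 0.539, for macrophage identity. Fry's test for changes in either direction passed for chemokines (adjusted p = 0.00167), alternative activation (0.00516), heat shock and immediate early genes (0.0168), the vitamin D receptor axis (0.0215) and interferon-inducible GTPases (0.0428). Of the 21 macrophage identity genes 1 fell, Trem2, and 6 adjusted over the list alone. Of 20 activation surface receptors 2 fell, Fcgr1 (-2.36 log2) and Cd14, and adjusted over the list alone 2 rose and 5 fell. Of 17 chemokine genes Ccl6 rose by 1.85 log2, Ccl4 rose by 1.89 log2 and Cxcl16 fell by 2.22 log2, with the same counts of 2 and 1 adjusted over the list alone. Of 15 MHC class I genes 1 fell, Psmb8, and 6 adjusted over the list alone. Of 12 alternative activation genes 2 rose, Mrc1 and Tgm2, and 3 adjusted over the list alone. With log2 of the Gapdh 3'/5' ratio as a covariate, 105 probe sets were called, 48 higher and 57 lower, of which 33 were among the 104. Psmb8 and Trem2 then had the opposite sign, at 1.19 and 0.41 log2. Cd14 (-1.45 log2, limma adjusted p = 0.323), C5ar1 (-1.24, 0.866) and Klf6 (-0.39, 0.975) were no longer called. That fit has 1 residual degree of freedom. The ratio was higher with calcitriol in both wild-type pairs (7.67 against 1.11, and 1.65 against 1.04), so the covariate is hard to part from calcitriol. Limma called 0 without the signal filter (1680 at an unadjusted p under 0.05), with a stricter filter (1082), without the intensity trend (1406) and in an additive fit without the 2 arrays with the highest 3'/5' ratios (1798), 58 after quantile normalization, 5 with a lower floor, 22 in an additive fit with the covariate (15 higher, 7 lower) and 20 with the labels of the 2 untreated arrays exchanged (14 higher, 6 lower).

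The same contrast in Vdr-/- cells gave the background of calcitriol where the receptor gene was disrupted. There Slfn2 rose by 2.64 log2 (SE 0.359, limma adjusted p = 0.00163), and Cybb, the NADPH oxidase subunit gene, by 2.43 log2 (SE 0.352, adjusted p = 0.003). The test called 35 probe sets, all higher with calcitriol, for 31 named genes, and 1146 had an unadjusted p under 0.05. Tlr8, a sensor of single-stranded RNA, rose by 4.46 log2, Get3 by 3.45 log2 and the proteasome gene Psmb7 by 3.40 log2, each with the array labelled Vdr-/- untreated at the floor. Arhgdib, Trpv2, Sbds, Psmb9 and Ptpn6 rose by 2.21, 2.10, 1.98, 1.93 and 1.90 log2, but only 1 of 2 probe sets of Ptpn6 rose. Cd14 had a log2 change of 0.57 (adjusted p = 0.899). The lowest fry adjusted p of the lists was 0.799, and Cd68, of macrophage identity, rose by 1.66 log2. The array labelled Vdr-/- untreated had the second highest 3'/5' ratios. The Gapdh ratio was raised on both Vdr-/- arrays without calcitriol (4.82 and 3.06) and low on both with it (0.853 and 1.07). It thus ran with calcitriol in both pairs, although actin and ThrX were clearly raised on the untreated array only. Slfn2 read 233.3 and 383.5 without calcitriol and 2073 and 1685 with it. With the Gapdh ratio as a covariate 88 probe sets were called, 18 higher and 70 lower, of which 3 were among the 35. That fit has 1 residual degree of freedom, and a covariate that runs with calcitriol is hard to part from it. Limma called 0 without the signal filter (1046 at an unadjusted p under 0.05), with a stricter filter (599), without the intensity trend (1017) and in an additive fit without the 2 arrays with the highest ratios (740) and with the labels of the 2 untreated arrays exchanged (610).

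The difference between the calcitriol effects of the genotypes was tested to ask which changes depend on the receptor. The calcitriol effect on Cd14 was lower in wild type than in Vdr-/- (log2 difference -2.73, SE 0.518, limma adjusted p = 0.00565). The difference was -4.64 for Slfn2 (SE 0.508, adjusted p = 7.63e-05), -6.45 for C5ar1 (SE 0.978, adjusted p = 0.00113) and -4.80 for Trem2 (SE 0.796, adjusted p = 0.00243). It was 3.31 for Hopx (SE 0.704, adjusted p = 0.0133) and 2.61 for the kinase gene Hipk2 (SE 0.485, adjusted p = 0.0048). Without IFN-gamma, Trem2 read 301.9 with calcitriol in wild type and 402.4 on the array labelled Vdr-/- untreated, against 5682 and 5417 on the other arrays. C5ar1 read 15.5 and 70 against 563.6 and 605.1. Cd14 and Slfn2 were also lowest, and Hopx and Hipk2 highest, on these arrays with the highest 3'/5' ratios. On the arrays without IFN-gamma, receptor action thus cannot be told apart from truncation for these genes. With IFN-gamma, Hopx read 152.1 without and 2000 with calcitriol in wild type, against 123.7 and 94.2 in Vdr-/-. Cd14 read 935.8 and 228.3 against 1037 and 835.1. Slfn2, C5ar1, Trem2 and Hipk2 also kept their direction there, but all were called in a fit that includes these arrays. Each value is 1 array, and the Vdr-/- IFN-gamma array had a raised Gapdh ratio (3.06), so these values do not settle it.

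In all, 271 probe sets differed, 31 with a higher and 240 with a lower calcitriol effect in wild type, and 2196 had an unadjusted p under 0.05. The 240 had a median change of -1.46 log2 with calcitriol in wild type and of 1.44 log2 in Vdr-/-, so they combine falls in wild type with rises in Vdr-/-, measured in part against the array labelled Vdr-/- untreated. Ifitm6, Bhlhe40, Itgb7 and Zbtb21 had differences of 4.62, 4.42, 3.74 and 2.65 log2. Klf9, a Krüppel-like factor gene, had 2.54 log2, Hgsnat 2.56 log2 and 4931406C07Rik 2.73 log2. On the lower side, Tlr8 had -7.16, Pck2 -5.86, Tm2d3 -5.75, Klf6 -4.79, Psmb7 -4.76, Get3 -4.69 and Pltp -4.54 log2. Tlr8, C5ar1, Tm2d3, Psmb7 and Get3 had arrays at the floor, as did Ifitm6, Bhlhe40 and Itgb7, so the size and order of these differences depend on the floor. Macrophage identity genes were lower for 5 of 21, and 6 adjusted over the list alone, among them the complement genes C1qb (-2.90 log2) and C1qa (-2.41 log2) and the lysosomal gene Cd68 (-2.70 log2). Of 15 MHC class I genes 4 were lower, and 5 adjusted over the list alone, such as Psmb9 (-3.09 log2) and Psme1 (-2.90 log2). Of 20 activation surface receptors 1 was higher, the integrin gene Itgax (2.32 log2), and 3 were lower, among them Fcgr1 (-3.79 log2) and Itgam (-3.63 log2), while adjusted over the list alone 2 were higher and 5 lower. The lowest fry adjusted p of the lists was 0.467, and for changes in either direction alternative activation had 0.0106. With the Gapdh 3'/5' ratio as a covariate 73 probe sets were called, 40 higher and 33 lower, of which 20 were among the 271, and both arrays with the highest ratios were part of this contrast. Limma called 0 without the signal filter (2028 at an unadjusted p under 0.05), with a stricter filter (1379), without the intensity trend (1612), in an additive fit without those 2 arrays (1174) and with the labels of the 2 untreated arrays exchanged (1126), and 100 with a lower floor.

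Vdr-/- cells were compared with wild-type cells over the 4 treatments, with and without calcitriol, to ask what differs between the genotypes on average. A genotype difference that depends on the treatment adds to the spread of this test. A count of 0 thus does not show that the receptor changes nothing. No gene passed the limma test, with 0 of 18054 probe sets called and 611 at an unadjusted p under 0.05, where 903 would be met by chance. Vdr had a log2 difference of -0.81 (adjusted p = 0.999) and Cyp24a1 of -1.43 (0.999). A second Cyp24a1 probe set went the other way. It read 105.8 on the array labelled Vdr-/- untreated, its highest value, and 3.7 on the array labelled wild-type untreated. Cd14 had 0.78, Irf1 0.39 and Cxcl9 -0.19 log2, each with an adjusted p of 0.999. The lowest fry adjusted p of the lists was 0.482, for dendritic cell markers, which had 0.000745 for changes in either direction. With the Gapdh ratio as a covariate 86 probe sets were called, 60 higher and 26 lower in Vdr-/-, and with the labels of the untreated arrays exchanged 7 were called.

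The IFN-gamma effect was also compared between the genotypes. No gene was shown to respond differently, since limma called 0 probe sets and 634 had an unadjusted p under 0.05. The difference, wild type minus Vdr-/-, was -0.33 log2 for Cxcl9, 0.64 for Irf1, -1.06 for Ciita and -0.26 for Cd74, each with an adjusted p of 0.996. The lowest fry adjusted p of the lists was 0.893. With the Gapdh ratio as a covariate 7 probe sets were called, and with the labels of the untreated arrays exchanged 109, of which 101 were higher and 8 lower.

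The effect of calcitriol on IFN-gamma treated wild-type cells addressed the question in the title of the series, how the hormone bears on IFN-gamma dependent expression. In the wild-type pair, genes chosen in Vdr-/- cells as at least 2-fold higher with IFN-gamma had a median change with calcitriol of -0.17 log2 (330 genes, bootstrap 95% interval -0.263 to -0.0138). Of these, 71 were at least 2-fold lower and 48 at least 2-fold higher, and the median lay at percentile 0.02 of 10000 random sets matched on signal. In the Vdr-/- pair, 405 genes chosen in wild-type cells had a median of 0.0084 log2 (0 to 0.0451), at percentile 99.2. Genes at least 4-fold higher had medians of -0.198 log2 (75 genes) and 0.0824 log2 (101 genes). Genes chosen as at least 2-fold lower with IFN-gamma had medians of 0 in both pairs, at percentiles 89.9 in wild type and 99.9 in Vdr-/-. A gene at the floor on both arrays has a change of exactly 0, so these medians and percentiles may reflect the floor and decide nothing. Of these genes, 107 were at least 2-fold lower and 91 higher in wild type, and 102 and 71 in Vdr-/-. Each pair is 1 array against 1, so these intervals and percentiles cover the choice of genes only, and the difference between the genotypes was not tested.

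With the spread taken from the Vdr-/- arrays, which takes calcitriol to have no effect there, limma called 0 probe sets for calcitriol under IFN-gamma (1494 at an unadjusted p under 0.05). It called 0 without IFN-gamma (2258) and 0 for the interplay of both treatments (1821). Under IFN-gamma the log2 change was -2.04 for Cd14 (adjusted p = 0.625), -0.68 for Cxcl9 (0.61), -1.02 for Ciita (0.693), -0.29 for Irf1 (0.858) and -0.38 for Cd74 (0.922). It was 1.91 for Cyp24a1 (0.604), 1.43 for Vdr (0.871), 2.13 for Nos2 (0.673), -0.57 for Tnf (0.777) and 2.25 for Il12b (0.737). With the spread from the product of all 3 factors instead, 126, 146 and 8 probe sets were called. These single pairs have no replicate, and the counts rose to between 447 and 1547 without the filter or with a higher floor, where 73.9% to 84.2% of the calls had Vdr-/- arrays tied at the floor.

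A comparison of the wild-type array with both treatments against the other 3 IFN-gamma arrays was added after the values had been seen. Its p-values hold no variation of the single array and rank genes only. That array had the highest 3'/5' ratios of the 4 for ThrX (4.14 against 2.78 to 3.63) and actin (1.81 against 1.48 to 1.63), and a Gapdh ratio of 1.65 against 1.04 to 3.06. On that array Ccl6, a chemokine gene, was 3.82 log2 higher (9237 against 395.2 to 1321, limma adjusted p = 0.00946). Hopx was 4.05 log2 higher and the small LIM protein gene Crip1 2.62 log2 higher. Cd14 was lower there (-2.03 log2, 228.3 against 835.1 to 1037, adjusted p = 0.0113). The interferon-induced chemokine gene Cxcl10 was lower (-2.18 log2, 268.4 against 1171 to 1279, adjusted p = 0.00773) and the Fc receptor gene Fcgr1 too (-2.10 log2, adjusted p = 0.0484), both chosen after their values were seen. Of 10606 probe sets 157 were called, 44 higher and 113 lower, for 29 and 67 named genes, and 1428 had an unadjusted p under 0.05.

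Further genes higher on that array were Ifitm6, Pdgfa, Jdp2, Itgax, Sdc1, 4931406C07Rik and Dnmt3a, by 4.31, 2.99, 2.92, 2.68, 2.41, 2.40 and 2.36 log2. Tnfrsf13b and Plxdc1 were at the floor there, at least 13.5-fold and 11.4-fold lower than on the other 3 arrays, and so was Stap1, at least 9.65-fold lower. Also lower were Olfml3 (-3.66 log2), Rnase4 (-3.62), 1600014C10Rik (-3.54), Ankrd44 (-3.38), Clec4a2 (-3.36), Pck2 (-3.31) and Abcb8 (-3.14). Probe sets induced and probe sets repressed by IFN-gamma were found among both the lower and the higher ones on that array. Both kinds had been called in a fit that includes this array, so they do not show whether calcitriol opposes IFN-gamma. Other chemokine genes called were Cxcl16 (-1.87 log2) and Ccl4 (1.80 log2). Among interferon-responsive genes Ifit3 (-3.08 log2, adjusted p = 0.0116) and Gbp2b (-1.23 log2, 0.0306) were lower. Not called were Cxcl9 (-0.43 log2, 0.469), Irf1 (-0.24, 0.681), Cd74 (-0.17, 0.802), Ciita (-0.73, 0.407), Gbp2 (0.51, 0.553) and Tnf (-0.41, 0.68). Vdr was 2.31 log2 higher (adjusted p = 0.244) and Cyp24a1 2.75 log2 higher (0.476), neither called. The comparison treats 3 arrays of unlike genotype and treatment as repeats and holds no variation of the array singled out, so its p-values rank genes only, and it gave 346 calls, 318 higher and 28 lower, before probe sets at the floor were removed. It cannot part calcitriol from anything else particular to that 1 array.

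**Figure D3:**
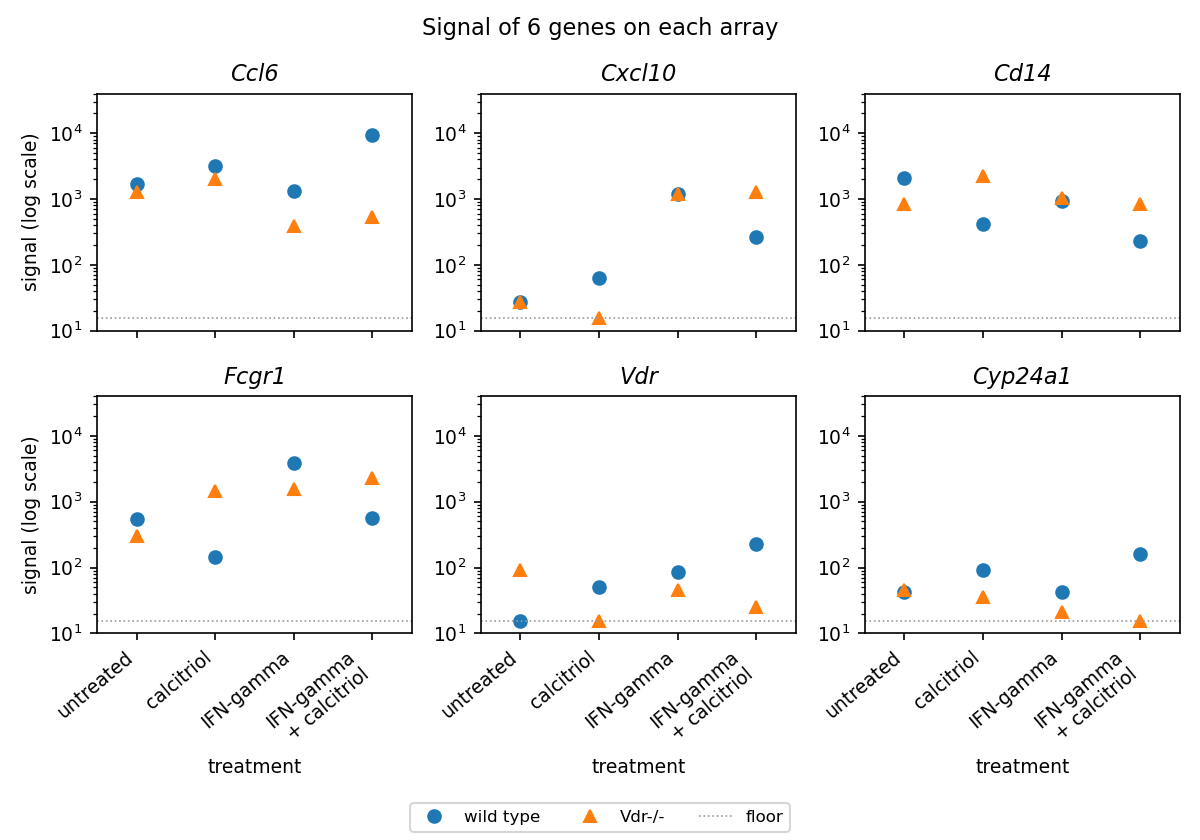
Probe set signal (log scale, floor of 15.5 as a dotted line) of 6 genes by treatment, with 1 point per array for wild type and for Vdr-/-. Cd14 read 422.3 and 228.3 on the wild-type arrays with calcitriol against 2052 and 935.8 without it, and Ccl6 read 9237 on the wild-type array with both treatments.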

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

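The tests of the calcitriol difference between the genotypes were chosen only after the result was seen, and the tests of the Vdr signal were set before their outcome was known.

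The calcitriol effect, wild type minus Vdr-/-, differed in a limma test of the difference itself for 271 probe sets. Named genes with a higher effect in wild type were Ifitm6 (4.62 log2), Bhlhe40 (4.42), Itgb7 (3.74), Hopx (3.31), 4931406C07Rik (2.73), Zbtb21 (2.65), Hipk2 (2.61), Hgsnat (2.56), Klf9 (2.54) and Marveld1 (2.5). Those with a lower effect were Tlr8 (-7.16), C5ar1 (-6.45), Pck2 (-5.86), Tm2d3 (-5.75), Trem2 (-4.80), Klf6 (-4.79), Psmb7 (-4.76), Get3 (-4.69), Slfn2 (-4.64), Pltp (-4.54) and Cd14 (-2.73).

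With the labels of the 2 untreated arrays exchanged, limma called 0 probe sets for this difference (1126 at an unadjusted p under 0.05). The difference thus rests on labels that the Vdr signal does not follow, although the Vdr probe sets may check nothing about the genotype. Calcitriol acting only through the receptor cannot be excluded, since the answer depends on the labels. The 32 genes used were called lower on the wild-type arrays alone (median -2.35 log2), a choice apart from the 59 named genes of the main fit. As labelled, their median change in Vdr-/- was 0.805 log2 (0.549 to 1.26, random sets -0.243 to 0.164). On the IFN-gamma arrays alone it was 0.216 (0.0145 to 0.503, random sets -0.164 to 0.147), but the Vdr-/- IFN-gamma array also had a raised Gapdh ratio (3.06). With the labels exchanged, the 32 largest falls had -0.1 (-0.417 to 0.339, random sets -0.395 to 0.212). Truncated RNA on the wild-type calcitriol array and the array labelled Vdr-/- untreated may also contribute, as the median difference over the called probe sets was 3.72 log2 without IFN-gamma, where both arrays lie, and 2.06 log2 with it, or 55.3% (48.6 to 60.1), a share that calling against the spread between these pairs pushes up. The same contrast of log2 3'/5' ratios with IFN-gamma was 41% of that without for Gapdh (2.17 and 5.29), 7.39% for actin (0.2 and 2.7) and 10% for ThrX (0.766 and 7.66). Truncation and receptor action cannot be told apart here, because the same untreated array carries the truncation and the doubted label.

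Vdr read higher on the array labelled Vdr-/- untreated than on the array labelled wild-type untreated, by 2.54 log2 after flooring, against its direction in the other 3 treatments. Scatter of low signals is a candidate explanation, since 9.76% of 902 probe sets of like signal differed as much between these arrays, but this tests 1 Vdr probe set and leaves aside the second, which read 5.3 and 63.2 there in the same direction. Swapped genotype labels of the untreated arrays cannot be told apart from correct ones by the test run. Genes at least 2-fold apart between the genotypes in each of the other 3 treatments (5 higher and 18 lower) were separated by 0.759 log2 in the labelled direction, but random sets ranged from -1.47 to 1.36. No biological explanation was tested for this signal.

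The 3'/5' ratios of control probe sets, which were not part of the planned comparisons, stood out on 3 arrays. The Gapdh ratio was 7.67 on the wild-type calcitriol array, 4.82 on the array labelled Vdr-/- untreated and 3.06 on the Vdr-/- IFN-gamma array, against 0.853 to 1.65 on the others. The ThrX ratio was 72.8 and 18.4 on the first 2 of these arrays, against at most 4.14 on the others.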

How the results depend on the processing

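Tests with the Gapdh ratio as a covariate, without the 2 truncated arrays (the highest 3'/5' ratios), in additive calcitriol fits, with the labels of the 2 untreated arrays exchanged and with 1 IFN-gamma array against 3 were chosen only after the results were seen. No paired analysis was possible because each group has 1 array and no replicate number links mice or cultures. The array pairs fitted as blocks are matched by their labels alone. IFN-gamma pairs share genotype and calcitriol treatment, and genotype pairs share treatment. Counts are of probe sets called by limma, and the cause was not tested unless given. IFN-gamma calls (619) were 437 to 638 with quantile normalization, a stricter filter, other floors, the covariate or the labels exchanged. They were 80 without a filter, 70 without the intensity trend, 402 without blocks, 394 with additive covariates, and 99 to 420 with a pair left out. Without the truncated arrays they were 0 (1395 at an unadjusted p under 0.05; 1 residual degree of freedom) and 53 with additive covariates. Genotype calls stayed 0 (218 to 796 unadjusted) except with the covariate (86) and the labels exchanged (7). These gave 7 and 109 for the IFN-gamma difference, otherwise 0 (236 to 867 unadjusted).

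Calcitriol in wild type (104) gave 58 after quantile normalization, 5 with a lower floor, 135 with a higher floor, 105 with the covariate (48 higher, 57 lower, 33 shared), 15 in an additive fit, 22 in one with the covariate (15 higher, 7 lower), 20 with the labels exchanged (17 shared) and 0 without the truncated arrays (1798 unadjusted). With the covariate Psmb8 and Trem2 reversed to 1.19 and 0.41 log2. With the mean over a gene's probe sets 1600014C10Rik was -0.29 (-2.95 for its brightest), Klf6 -1.73 and Hopx 1.63 log2, none called. Here a gene is the same if it stayed called or stayed not called, whatever its value, and weaker if its call was lost. Of the largest changes with calcitriol in wild type and the genes always reported, 7 were weaker after quantile normalization (23 the same). With the mean over a gene's probe sets 21 were weaker, so no called gene kept its call, and the 9 the same had not been called. With the covariate 12 were weaker (16 the same, though Ifitm6 went from 3.76 to 5.92 log2). In the additive fit with it 18 were weaker (12 the same). For IFN-gamma 28 or 29 genes were the same by call in each of the first 3 settings. Values still moved, as with the mean over probe sets Tfrc went from -2.7 to -1.68 and Gbp2 from 6.82 to 6.04 log2. Dio2 was weaker (-1.78, not called) with the mean over probe sets, and Tnf was stronger (1.81, called) with the covariate. Calcitriol in Vdr-/- (35) gave 18, 1, 59 and 88 with quantile normalization, a lower floor, a higher floor and the covariate. The difference (271) gave 220, 100, 339 and 73. With the labels exchanged both were 0 (610 and 1126 unadjusted). All 3 counts were 0 without a filter (1680, 1046 and 2028 unadjusted), with a stricter filter (1082, 599 and 1379) and without the trend (1406, 1017 and 1612). Without the truncated arrays, an additive fit with calcitriol by genotype gave 0 for all 3 (1406, 740 and 1174 unadjusted; 1 residual degree of freedom). The nested fit could not be made without them, and with the covariate it had 1 residual degree of freedom.

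For calcitriol in wild type under IFN-gamma, without it, and their interplay, counts of 0 became 447, 617 and 717 without a filter and 789, 1291 and 1547 with a higher floor. Between 73.9% and 84.2% of these had Vdr-/- arrays tied at the floor, which leaves no spread. Spread from the 3-way product gave 126, 146 and 8. Without IFN-gamma, a stricter filter gave 3 and a lower floor 5. Under IFN-gamma, 1 array against 3 gave 157 (44 higher, 113 lower), or 346 with floor ties kept (318 higher, 28 lower). The median shift of induced genes (-0.17) was -0.133 to -0.223 in its 5 alternatives. Signals near the floor of 15.5, such as those of Vdr, Cyp24a1, Nos2 and Il12b, limit what can be shown.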

Other observations

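The list shifts, the tests of the wild-type array with both treatments, the values of other probe sets of a gene and the counts over other splits of the arrays were chosen only after the results were seen.

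Between the 2 wild-type IFN-gamma arrays, with and without calcitriol, several gene lists had medians apart from most of 10000 random lists of equal size matched on signal. This is 1 array against 1 and gives no p-value, and nothing parts calcitriol from other differences between them. The 20 activation surface receptors had a median of -1.03 log2 (percentile 0) in wild type and 0.133 (percentile 90) in Vdr-/-. The 30 cell cycle genes had a median of 0.911 log2 (percentile 100) in wild type and -0.129 (20.8) in Vdr-/-, although 0 of 21 tested were called by limma when that array was set against the other 3. Macrophage identity genes had -0.446 log2 (0.07) and 0.105 (91.6), MHC class I genes -0.469 (0.66) and -0.017 (50.9), and type I interferon-stimulated genes -0.453 (0.7) and 0.392 (99.9). Interferon-inducible GTPases had -0.157 log2 (23.7) and MHC class II genes -0.268 (9.87) in wild type. The difference between the genotypes was not tested for these lists. In Vdr-/- cells, 0 of 24 type I interferon-stimulated genes were called for calcitriol over all genes and 11 were higher adjusted over the list alone (fry adjusted p = 0.799).

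Some genes with several probe sets gave values that differed by probe set. For Csf1r, the M-CSF receptor gene, 1 of its 3 probe sets read 1024 on the wild-type calcitriol array and 1016 on the array labelled Vdr-/- untreated, against 3853 to 4642 on 5 others and 1315 on the wild-type array with both treatments. The brightest Csf1r probe set read 23150 and 23760 on the first 2 arrays, against 14810 to 18890 on those 5 and 9768 on the array with both treatments. Over the genes at least 2-fold lower on the array with both treatments than on each other IFN-gamma array, 59 of 67 further probe sets of 46 genes were also lower there (median -1.40 log2). On the wild-type calcitriol array, 39 of these 67 were lower than on the array labelled wild-type untreated (median -0.293 log2). On the array labelled Vdr-/- untreated, 39 of the 67 were also lower than on the Vdr-/- calcitriol array (median -0.203 log2). Of 50 further probe sets of the genes at least 2-fold higher, 46 were higher on the array with both treatments (median 1.32 log2), 39 on the wild-type calcitriol array (0.758) and 31 on the array labelled Vdr-/- untreated (0.315).

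The wild-type array with both treatments had 128 genes at least 2-fold higher and 161 at least 2-fold lower than on each of the other 3 IFN-gamma arrays. No such count is given for those arrays, so these counts have no baseline. Its r with the other 3 was 0.839 to 0.86, against 0.864 to 0.897 among them. The same genes were separated by 0.862 log2 between the wild-type calcitriol array and the array labelled Vdr-/- untreated, outside the range of random sets (-0.165 to 0.174). Calcitriol acting through the receptor, a fault of that 1 array, swapped labels of those 2 arrays and 3'-truncated labelling cannot be told apart, because these 2 arrays also differ in truncation, and the genes were also separated by 0.572 log2 (0.362 to 0.898) between the array labelled Vdr-/- untreated and the Vdr-/- calcitriol array, which differ in truncation and where receptor action predicts about 0. Between 2 arrays with low ratios, Vdr-/- calcitriol and the array labelled wild-type untreated, they were separated by -0.358 log2, also outside the random range (-0.159 to 0.134). Wild-type calcitriol minus the array labelled wild-type untreated gave 1.06 log2 (0.904 to 1.38), and the array labelled Vdr-/- untreated minus that array gave 0.317 log2.

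Over the 35 splits of the 8 arrays into 4 and 4, a limma fit of 2 groups called 402 probe sets for IFN-gamma and at most 16 for any other split. Only 1 of 35 splits, the real one, called as many. As 1 of 35 is the smallest share that these splits can give, a chance split is made unlikely but is not excluded. For genotype the fit of 2 groups called 0 (567 at an unadjusted p under 0.05) and the highest other count was 402, the IFN-gamma split. With a count of 0 each of the 35 splits calls at least as many whatever the data, so this decides nothing.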
